A study of Mus musculus with 4 samples.

How the data were processed

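Renal cortex was profiled by Drop-seq, a droplet method in which each captured mRNA molecule receives a cell barcode of 12 bases and a unique molecular identifier (UMI) of 8 bases. The series holds 4 libraries, 2 from Akita mice (C57BL/6-Ins2Akita, which carry a mutated copy of the insulin gene Ins2 and become diabetic) and 2 from wild-type mice. Per the labels, the Akita mice were 116 and 119 days old and the wild-type mice 45 and 51 days old, so age ran with genotype and could not be a covariate. The growth protocol in the labels gives 24 weeks of housing, longer than any of these ages. It gives 8 mice per group, of which 2 per group were sequenced.

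The deposited files hold UMI counts per gene and barcode, with no normalization. The submitters' processing notes name UMI-tools 0.5.3, STAR 2.5.2b, featureCounts 1.6.0 and the GRCm38 mouse genome. No filter on cells or genes is recorded in them. Each file listed 1998 or 2000 barcode strings. In each file, 4 strings were not barcodes (a run of undetermined bases, or at least 11 identical bases), and these held between 1.08% and 1.33% of the UMIs and were left out. Between 19 and 26 gene identifiers per file had no symbol in the GENCODE annotation, at most 0.0410% of the UMIs, and kept their identifier. Coordinates are 1-based on GRCm38.

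A barcode was retained as a cell when it had at least 200 detected genes and at most 50% of its UMIs from mitochondrially encoded genes. CPM values relate each gene's UMIs to all UMIs summed over the retained cells. The retained cells of all libraries were clustered together with scanpy 1.11.5 and leidenalg 0.10.2 (counts scaled to 10000 per cell, log-transformed, 2000 variable genes, 30 principal components, 15 neighbours, Leiden resolution 1, and 1 further split of clusters of at least 50 cells that had at least 3 markers of a second class among their top 50 genes). A cluster was called after the cell type with the most markers among its top 50 genes by fold, at least 3 and more than any other type, unless another type had more markers among its top 10 genes or, in a cluster of low depth, none of its own was there. Clusters left without a name by a comparison with all other cells were compared again with the cells named other than proximal tubule, and those still failing stayed unnamed. The markers of 16 classes, the tests, the gene lists and the rule for naming genes were fixed before the data were examined. Doublets were called per library with Scrublet in scanpy, which marked 7 cells, and these were kept.

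Cells were not used as replicates. UMI counts were summed per library, over all retained cells, over the proximal tubule-like cells, and over any other named class with at least 20 cells in every library. Sums were compared between 2 Akita and 2 wild-type libraries with edgeR 4.0.16 in R 4.3.3 (TMM factors, filterByExpr, quasi-likelihood test, two-sided) with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. DESeq2 1.42.0 and limma 3.58.1 (voom) were run beside it. Of 24 gene lists, those with at least 4 tested members were tested with limma's camera at a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. Shares of cells and library measures were compared with an exact two-sided permutation test of the difference of means, whose smallest possible p with 2 against 2 is 0.3333. Intervals for shares are exact binomial (Clopper-Pearson) at 95% and, like the limit of 3 counts allowed by a count of 0, cover counting error only.

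Named genes were to be those with an adjusted p under 0.05, a mean of at least 50 CPM and both Akita libraries on one side of both wild-type libraries, up to 10 per direction. Where fewer than 5 passed in a direction, the 5 with the smallest p and at least 50 CPM are named and stated not to pass (3 for a class other than the proximal tubule). Of the 4 members of each list with the highest CPM, 3 or all 4 are named too, as a range over those named, or every tested member where a list had fewer.

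The alternatives fixed beforehand were other size factors, tools and filters on low counts, a replicate block, each library left out, at least 500 genes or at most 25% mitochondrial UMIs per cell, doublets removed, every deposited barcode used, other Leiden resolutions, each library clustered on its own, mitochondrial and haemoglobin genes left out, and counts thinned to the smallest library. Because many barcodes turned out to be present in the files of both Akita replicate 2 and Wild-type replicate 1, alternatives chosen after seeing the data either left these out or kept each in 1 file, whichever the ratio of its UMIs was closer to. Each barcode's ratio was assigned to the nearer of the 2 modes, and a barcode was kept in the file with relatively more of its UMIs, which is an assumption. A crossed replicate block, the replicate block in DESeq2 and limma-voom with each shared barcode kept in 1 file, all deposited strings, and barcodes with the same first 11 bases counted once were also added.

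The tests were tested on simulated data drawn from the real means and dispersions, with 200 changed genes of at least 50 CPM. In whole-suspension sums, 62 of 100 genes changed 2-fold and 99 of 100 changed 4-fold were recovered (40 and 93 with each shared barcode kept in 1 file). In proximal tubule-like sums 46 and 98 were recovered (30 and 91 with each shared barcode kept in 1 file). Between 6 and 9 unchanged genes were called in each simulation. The simulated libraries were independent, while Akita replicate 2 and Wild-type replicate 1 as deposited hold many of the same barcodes. The simulated recovery can therefore overstate that in the files as deposited.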

Results

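Drop-seq measured mRNA in dissociated renal cortex of 2 Akita mice, a model of type 1 diabetes, and 2 wild-type mice, 1 library per mouse. Akita replicate 1 held 1016719 UMIs in all, Akita replicate 2 held 1200209, Wild-type replicate 1 held 1303453 and Wild-type replicate 2 held 1115055. The retained cells numbered 311 and 600 in the Akita libraries and 564 and 441 in the wild-type libraries, 1916 in all. Among them, 98 and 96 in the Akita libraries and 108 and 105 in the wild-type libraries differed by 1 base from another retained barcode of their file. That made 407 barcodes, and whether each is a separate cell was not tested. The intervals for shares below count every retained barcode as a cell. The retained cells carried between 54.9% and 63.1% of each file's UMIs. The median retained cell had 791 ± 62.6 UMIs in Akita and 801 ± 26.2 in wild type (mean ± SD of 2 library medians), a difference of −9.75 UMIs (exact permutation p 1.00). Mitochondrially encoded genes took a median of 18.9 ± 0.630% of a cell's UMIs in Akita and 19.3 ± 1.34% in wild type (SD, n = 2; exact permutation p 1.00). Neither difference exceeded the spread between replicates. Every other library measure compared had an exact permutation p of 0.667 or 1.00.

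Ins2, the gene mutated in Akita mice and active in pancreatic islets, had 0 UMIs in all 4 files, which allows up to between 2.30 and 2.95 CPM, so genotype could not be read from it. Ins1 also had 0 UMIs. Xist, which marks female cells, had 0 UMIs in every file, while the Y-linked Ddx3y had 37 and 48 UMIs in the Akita files and 58 and 45 in the wild-type files. Eif2s3y, Uty and Kdm5d had UMIs in all 4 files too, the pattern of male mice. The genes with the most UMIs in the Akita libraries included the mitochondrial ribosomal RNA mt-Rnr2, Kap, which encodes an androgen-regulated protein of the proximal tubule, and the long non-coding RNA Malat1. Haemoglobin genes took between 0.00574% and 0.0525% of UMIs in retained cells.

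The files of Akita replicate 2 and Wild-type replicate 1 had 884 barcodes in common, where chance would give 0.237, and every other pair of files had 3 or 4. These shared barcodes made up 438 of the 600 retained cells of Akita replicate 2 (73.0%) and 454 of the 564 of Wild-type replicate 1 (80.5%), with 88.4% and 91.5% of the UMIs of those cells. Of the shared barcodes, 424 were retained in both files, and all 424 fell into the same cell class in both. The ratio of UMIs between the files had a pair of modes. At 363 barcodes the median ratio of Akita replicate 2 to Wild-type replicate 1 was 1.33, and at 521 it was 0.546, with 2 barcodes lying near the midpoint (within 0.2 log2 units). The values below therefore count most cells of these libraries in both groups, unless a value is said to keep each shared barcode in 1 file.

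**Figure D1:**
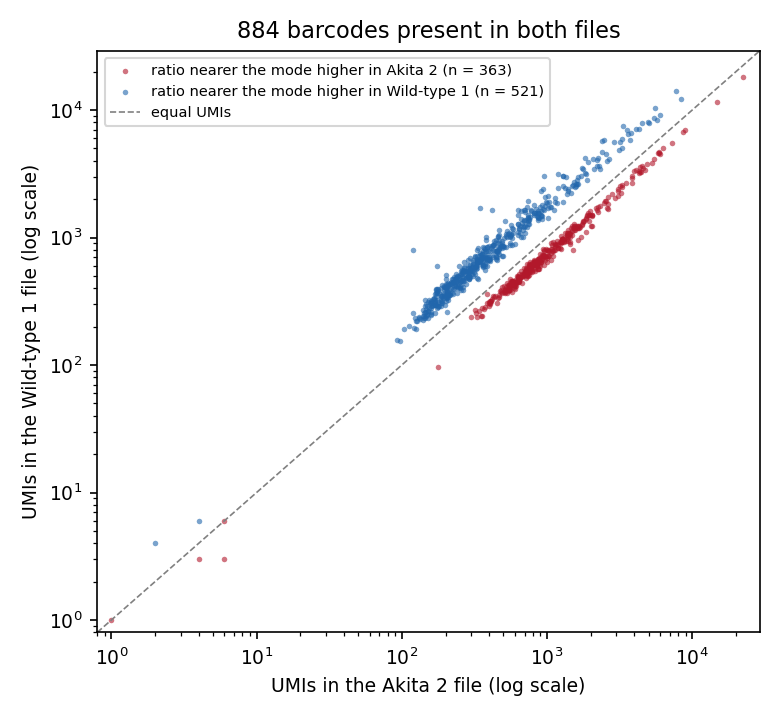
UMIs of each of the 884 shared barcodes in the Akita replicate 2 file (x axis, log scale) and in the Wild-type replicate 1 file (y axis, log scale). The points form a pair of bands, 363 barcodes at a median ratio of 1.33 and 521 at 0.546.

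The cell classes show which tubule segments the dissociated cortex yielded in each genotype. Proximal tubule-like cells, with Gatm, Slc34a1, Kap and Slc22a6 among their leading genes, were 1444 of the 1916 cells, in 6 clusters. Loop of Henle-like cells (203, led by Umod and Egf), intercalated-like cells (109, Atp6v1g3 and Slc26a4), distal convoluted tubule-like cells (73, Calb1, Trpm6 and Slc12a3) and macrophage or dendritic-like cells (15, Cd74 and H2-Ab1) were also found. Slc12a3 and Tmem52b were among the 10 leading genes of both the loop of Henle-like and the distal convoluted tubule-like cluster. The loop of Henle-like cluster was ranked against all other cells. The distal convoluted tubule-like cluster was ranked against the cells named other than proximal tubule, most of them loop of Henle-like. A place in both rankings therefore does not show whether these genes tell the classes apart. A cluster of 72 cells led by S100g, Klk1 and Calb1 stayed unnamed.

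Proximal tubule-like cells made up 75.6 ± 4.44% of retained cells in Akita and 75.7 ± 3.50% in wild type (SD, n = 2), a difference of −0.0780 percentage points (exact permutation p 1.00). Distal convoluted tubule-like cells made up 5.29 ± 2.06% in Akita and 2.87 ± 0.207% in wild type, with both Akita libraries above both wild-type ones (exact permutation p 0.3333, the smallest that 2 against 2 allows). The single Akita values were 6.75% (95% interval 4.23 to 10.1) and 3.83% (2.45 to 5.70), and the wild-type values were 3.01% (1.77 to 4.78) and 2.72% (1.41 to 4.70). Both Akita libraries were also above both wild-type ones with at least 500 genes per cell, at most 25% mitochondrial UMIs, doublets removed, barcodes with the same first 11 bases counted once, or each shared barcode kept in 1 file. The separation was absent in 4 further settings. At Leiden resolution 2 the Akita shares were 3.22% and 6.00% and the wild-type shares 3.90% and 4.08% (exact permutation p 1.00), and without the shared barcodes Akita replicate 2 had 2.47% against 2.72% in Wild-type replicate 2 (exact permutation p 0.667). With each library clustered on its own the class was found in Akita replicate 2 and Wild-type replicate 1 alone (exact permutation p 1.00), and at resolution 0.5 in no library. Intercalated-like cells made up 4.20 ± 2.31% and 6.74 ± 2.01% (exact permutation p 0.667), loop of Henle-like cells 10.8 ± 1.66% and 10.1 ± 0.766% (p 0.667, exact permutation). Macrophage or dendritic-like cells made up 0.827 ± 0.715% and 0.581 ± 0.181%, and the unnamed cluster 3.21 ± 1.82% and 3.98 ± 1.11%. With each shared barcode kept in 1 file, proximal tubule-like cells made up 73.4 ± 7.58% and 80.9 ± 10.9%, intercalated-like cells 5.22 ± 3.75% and 4.24 ± 5.54%, and distal convoluted tubule-like cells 5.11 ± 2.32% and 2.66 ± 0.0875%. The wild-type intercalated-like share then rested on 1 cell of 308 in Wild-type replicate 1 and 36 of 441 in Wild-type replicate 2. These shares rest on the assumed assignment of shared barcodes. Intercalated-like cells were 10.7% of the barcodes with relatively more UMIs in Akita replicate 2 and 0.505% of the others, so the opposite assignment would change the shares. Values with it were not computed.

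**Figure D2:**
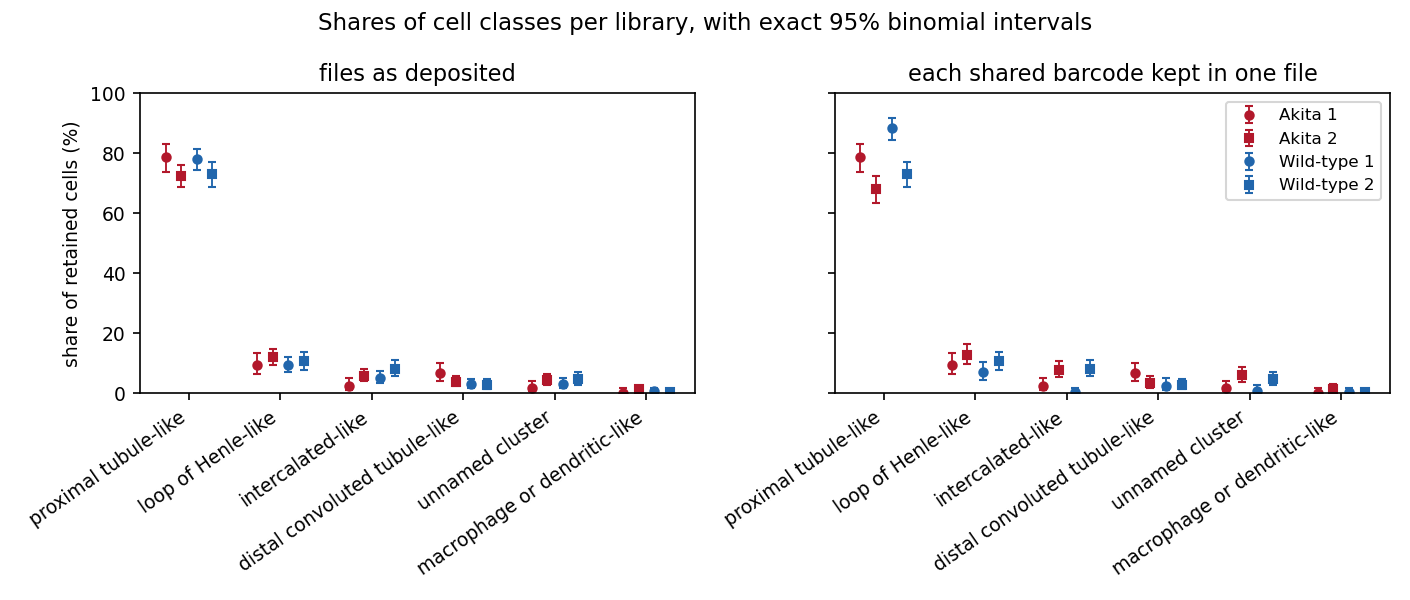
Share of retained cells (y axis, %) per cell class and library with exact binomial 95% intervals, for the files as deposited (left) and with each shared barcode kept in 1 file (right). Proximal tubule-like shares lie between 72.5% and 78.8% on the left and between 68.1% and 88.6% on the right.

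Transcripts of the proximal tubule were also counted in cells of other classes. Kap had a UMI in 97.1% of proximal tubule-like cells (41373 CPM, median 793 UMIs per cell) and in 95.6% of loop of Henle-like cells (5497 CPM, median 734 UMIs), which should lack it. Umod, made in the loop of Henle, had a UMI in 69.0% of loop of Henle-like cells and in 7.13% of proximal tubule-like cells (3348 and 53.6 CPM). Distal convoluted tubule-like cells had a UMI of it in 57.5% of cells (2323 CPM), far above the 208 CPM of intercalated-like cells. They were split from the same cluster as the loop of Henle-like cells, so that the separation of the classes is uncertain.

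The comparison of all retained cells asks which mRNAs differ between diabetic and wild-type cortex. Cyp51, an enzyme of cholesterol synthesis, and Trpm7, a channel-kinase that carries magnesium, had higher levels in both Akita libraries than in both wild-type libraries, and the proteasome subunit Psma1 and the fatty acid oxidation enzyme Acaa2 had lower levels, but no gene passed the test. By edgeR's quasi-likelihood test 0 of 7169 genes had an adjusted p under 0.05, 68 had an unadjusted p under 0.05, and DESeq2 and limma-voom also called 0 (7 and 57 at unadjusted p under 0.05). Chance would give 358 genes at unadjusted p under 0.05 in unrelated libraries. In the split with Akita replicate 2 and Wild-type replicate 1 on the same side, edgeR gave 971. Those 2 libraries hold mostly the same cells, which lowers the estimated spread, so the 971 cannot be read as genes that differ. With each shared barcode kept in 1 file this split gave 167 of 6306 genes, where chance would give 315. Most cells of Akita replicate 2 and Wild-type replicate 1 are counted in both groups. The 0 calls in the files as deposited, here and below, therefore do not show that few genes differ. Without Akita replicate 2, 23 genes were called, without Wild-type replicate 1, 14, without Akita replicate 1, 1, and without Wild-type replicate 2, 0. Leaving out Akita replicate 2 or Wild-type replicate 1 also takes away the overlap of cells between the groups, which the other leave-outs keep. These counts therefore do not show the weight of single libraries alone. With each shared barcode kept in 1 file 0 of 6306 genes were called by edgeR (199 at unadjusted p under 0.05), and DESeq2 and limma-voom also called 0. Chance would give 315 there, so the count was below chance also where no shared barcode was counted in both groups. The groups did not overlap at 902 genes higher in Akita and 790 lower, 23.6% of genes. Chance gives 33.3% for unrelated libraries, but most cells of Akita replicate 2 and Wild-type replicate 1 are counted in both groups. The 23.6% therefore cannot be read as fewer than chance. With each shared barcode kept in 1 file the groups did not overlap at 29.6% of genes. For genes of at least 500 CPM the median 95% interval reached 0.46 log2 units to either side before any adjustment over genes. In simulated whole-suspension sums 62 of 100 genes changed 2-fold were recovered (40 with each shared barcode kept in 1 file). Neither the interval nor the simulation, which drew independent libraries, allows for cells counted in both groups. The 62 can therefore overstate recovery in the files as deposited.

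Cyp51 (ENSMUSG00000001467, GRCm38 chromosome 5, 4081145 to 4104746) had 127 ± 5.51 CPM in Akita and 80.3 ± 3.05 CPM in wild type (SD, n = 2), a log2 fold change of 0.65 ± 0.25 (SE). Psma1 (ENSMUSG00000030751, chromosome 7, 114264606 to 114276118) had 75.6 ± 5.44 and 127 ± 11.03 CPM, −0.74 ± 0.25. Among the named genes with higher values in Akita, none of which passed, Slc25a30, Ubr3 and Trpm7 had log2 fold changes of 0.83, 0.77 and 0.52, each with the groups apart. Trpm7 was among the leading genes of the distal convoluted tubule-like cluster, whose share was 5.29% in Akita and 2.87% in wild type, and in proximal tubule-like cells alone it had 0.47 (edgeR adjusted p 0.999). ENSMUSG00000095041, which has no symbol and lies on the scaffold JH584304.1, had 0.78 with overlapping groups. Among those with lower values, Slc51a, a bile acid transporter subunit, had −1.04, the endoplasmic reticulum protein Reep3 −0.76, the neutral amino acid transporter Slc6a19 −0.69 and Acaa2 −0.51. Slc51a rested on Wild-type replicate 2, with 176 CPM against 53.8 to 55.6 CPM in the other libraries, and was called at −1.64 (edgeR adjusted p 0.0108) without Wild-type replicate 1, with −0.04 without Wild-type replicate 2. Without Akita replicate 2, ENSMUSG00000095041 was called at 1.11 (edgeR adjusted p 0.00458) and Slc6a19 at −1.25 (edgeR adjusted p 0.00813), and without Wild-type replicate 1 they had 1.44 (called, edgeR adjusted p 0.0448) and −0.28. Without Akita replicate 1, Slc25a30, Ubr3, Slc6a19, ENSMUSG00000095041 and Acaa2 had 0.44, 0.47, −0.32, 0.34 and −0.31, and without Wild-type replicate 2 Trpm7 and ENSMUSG00000095041 had 0.31 and 0.32. With each shared barcode kept in 1 file, Cyp51 had a log2 fold change of 1.09, Trpm7 0.79, Umod 0.71, Apom −1.10 and Slc6a19 −1.51, still short of the threshold (edgeR adjusted p from 0.833 to 1.00 for the 10 genes named there).

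Ces1g, a carboxylesterase gene with near-identical neighbours, is named after its values were seen, as the gene called most often in the alternatives. It had 0 and 4 UMIs in the Akita libraries, 4 in Wild-type replicate 1 and 69 in Wild-type replicate 2, and was the 1 gene called when no filter on low counts was used (log2 fold change −3.95, edgeR adjusted p 3.39e-07). It was also called without Akita replicate 1, without Akita replicate 2 and without Wild-type replicate 1, and 0 genes were called without Wild-type replicate 2.

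Proximal tubule-like cells were compared on their own because they reabsorb the filtered glucose load. Cyp2a4, a steroid hydroxylase gene that is higher in female mouse kidney, the beta-defensin gene Defb29, the ubiquitin ligase gene Ubr3 and Cyp51 had higher levels in both Akita libraries than in both wild-type libraries. Psma1, Reep3, Uap1l1 and the calcium-binding protein gene Calb1 had lower levels in both. None passed the test: edgeR called 0 of 6101 genes (58 at unadjusted p under 0.05), and DESeq2 and limma-voom called 0 (6 and 54). Chance would give 305 genes at unadjusted p under 0.05 in unrelated libraries. As cells are counted in both groups, the 0 calls do not show that few genes differ. Without Wild-type replicate 1 there were 12 calls, without Akita replicate 2 there were 11, without Akita replicate 1 there were 2 and without Wild-type replicate 2 there were 0. The groups did not overlap at 22.8% of genes. Chance gives 33.3% for unrelated libraries, which does not apply where cells are counted in both groups. With each shared barcode kept in 1 file the groups did not overlap at 29.4% of genes.

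Cyp2a4 (ENSMUSG00000074254, chromosome 7, 26307169 to 26315088) had 82.9 ± 19.2 CPM in Akita and 38.5 ± 10.9 CPM in wild type (SD, n = 2), a log2 fold change of 1.06 ± 0.34 (SE). Its near-identical paralog Cyp2a5 can share its reads, so its level is uncertain. Defb29 (ENSMUSG00000044249, chromosome 2, 152538714 to 152540098) had 163 ± 13.7 and 88.3 ± 55.9 CPM, 0.84 ± 0.34, with 1.77 (edgeR adjusted p 0.0405) without Wild-type replicate 1 and 0.29 without Wild-type replicate 2. The other named genes had log2 fold changes of 0.82 (Ubr3), 1.04 (Ccdc141, groups overlapping) and 0.64 (Cyp51) and of −0.96 (Psma1), −0.83 (Reep3), −0.95 (Calb1), −0.92 (Uap1l1) and −0.94 (Slc51a, groups overlapping). Single libraries moved several of these. Without Akita replicate 2, Ccdc141 had 1.63 and Uap1l1 −1.83 (both called, edgeR adjusted p 0.0111 and 0.0133), and without Akita replicate 1 they had 0.09 and −0.40. Calb1 had −0.49 and Slc51a 0.01 without Wild-type replicate 2, and Slc51a was called at −1.52 (edgeR adjusted p 0.0405) without Wild-type replicate 1. Reep3 had −0.56 without Akita replicate 1. Calb1 and Ccdc141 were also among the leading genes of the distal convoluted tubule-like cluster.

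With each shared barcode kept in 1 file, edgeR called 0 of 5280 genes in proximal tubule-like cells (140 at unadjusted p under 0.05, where chance would give 264), and DESeq2 and limma-voom 0. Defb29 then had 186 ± 19.4 CPM in Akita and 54.1 ± 7.47 CPM in wild type (SD, n = 2; log2 fold change 1.82 ± 0.32, SE; edgeR adjusted p 0.244). Cyp2a4 had 94.9 ± 2.31 and 26.1 ± 6.62 CPM (1.87 ± 0.38; edgeR adjusted p 0.454). With the replicate block as well, edgeR called 3 genes, among them Defb29 (adjusted p 0.00643) and Cyp2a4 (adjusted p 0.0470). With that block 260 genes had an unadjusted p under 0.05, where chance would give 264. DESeq2 and limma-voom with that block called 0 (19 and 224 at unadjusted p under 0.05). The sterol isomerase gene Ebp (1.22), Cyp51 (1.25) and the protease gene Napsa (1.11) had higher values in Akita, and Slc6a19 (−1.22), the lipocalin gene Apom (−0.90), Gm9616 (−1.18), Cpne3 (−0.90) and Reep3 (−0.98) lower ones, with adjusted p of 1.00 by edgeR.

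**Figure D3:**
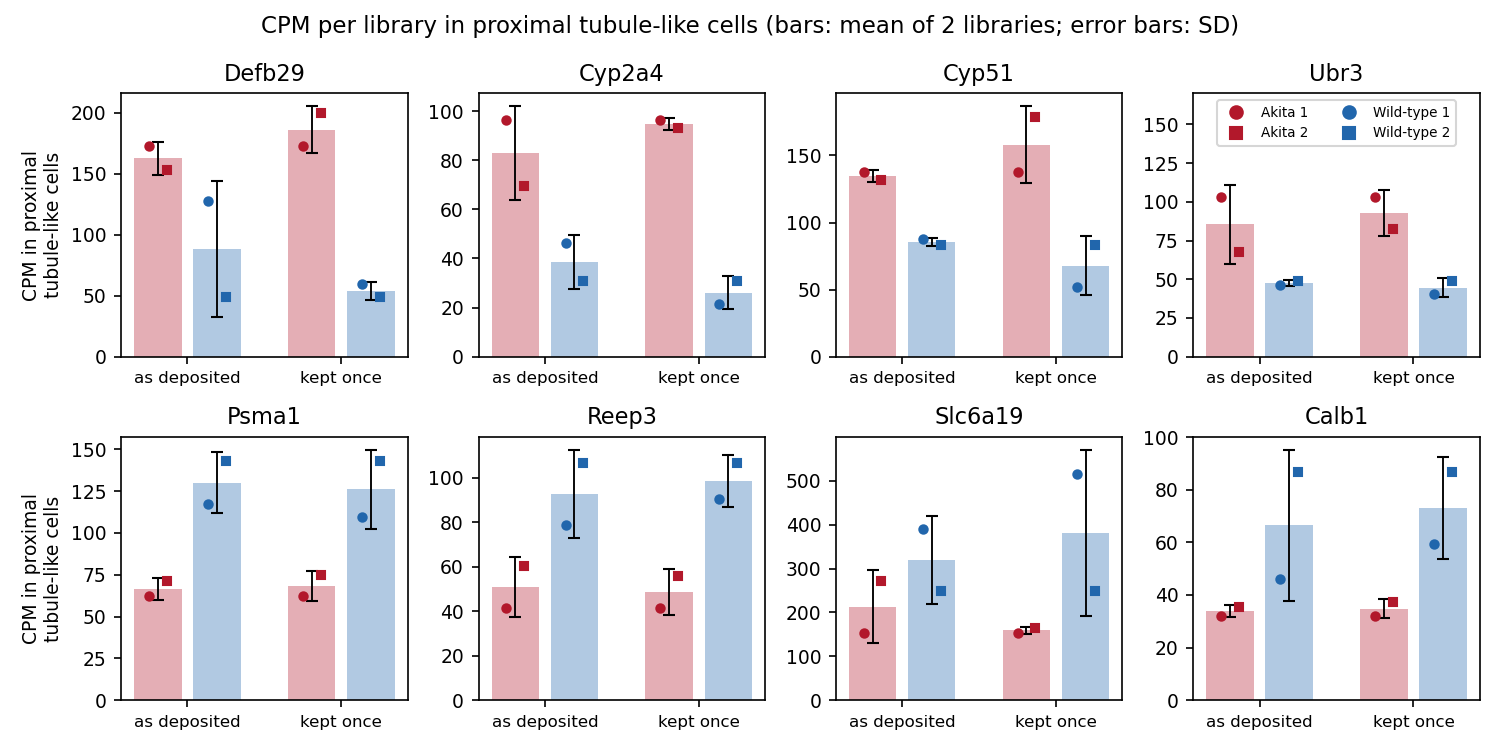
CPM (y axis) in proximal tubule-like cells of 8 named genes in each Akita and wild-type library, with bars at the mean and error bars of 1 SD (n = 2), for the files as deposited and with each shared barcode kept in 1 file. For Defb29 the wild-type mean falls from 88.3 CPM on the left to 54.1 CPM on the right while the Akita mean lies at 163 and 186 CPM.

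Loop of Henle-like cells were the only other class with at least 20 cells in every library. The mitochondrial transcripts mt-Rnr1 and mt-Te and the heterochromatin protein gene Cbx5 had higher levels in both Akita libraries, with log2 fold changes of 0.96, 0.61 and 0.64. The potassium channel gene Kcnj10 (−0.89), the ribosomal protein gene Rps4x (−0.96) and Slc25a5-ps (−0.71), a pseudogene whose reads can come from Slc25a5, had lower levels in both. Loop of Henle-like cells of Akita replicate 1 had a median of 26.6% mitochondrial UMIs, against 20.4% to 21.9% in the other libraries, and mt-Rnr1 had 0.44 without Akita replicate 1 and 1.37 (called, edgeR adjusted p 1.00e-06) without Akita replicate 2. Without Wild-type replicate 2, mt-Te had 0.38, Kcnj10 −0.46 and Rps4x −0.60. Cbx5 was also among the leading genes of the distal convoluted tubule-like cluster. None passed: edgeR called 0 of 709 genes (4 at unadjusted p under 0.05) and DESeq2 0 (2 at unadjusted p under 0.05). Leaving out Akita replicate 2 gave 17 calls, with 30 cells of 1 Akita mouse left, and leaving out any other library gave 0. With each shared barcode kept in 1 file 0 of 509 genes were called (21 at unadjusted p under 0.05).

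In the whole suspension of the files as deposited, camera called none of the energy metabolism lists (lowest adjusted p 0.314, fatty acid oxidation), though with each shared barcode kept in 1 file it called 3 of them, given below. The abundant fatty acid oxidation genes Acadm, Etfb and Acadl had log2 fold changes between −0.20 and 0.15, and the list's 27 tested genes a median of −0.09. Gluconeogenesis genes (Pck1, Fbp1 and Mdh1 between −0.12 and 0.47) had a median of −0.04, against which camera ranked the list upward. Glycolysis genes (Gapdh, Ldha, Tpi1 and Aldoa between −0.50 and −0.06) had −0.08, and glucose and fructose handling genes (Sord, Khk, Aldh2 and Slc2a2 between −0.13 and −0.05) had −0.08. Mitochondrially encoded transcripts (mt-Cytb, mt-Nd1, mt-Nd2 and mt-Co1 between −0.15 and 0.04) had −0.01 and nuclear-encoded oxidative phosphorylation genes (Cox4i1, Cox6c, Cox6a1 and Cox7b between 0.01 and 0.14) 0.02. Amino acid catabolism genes (Gatm, Ass1 and Dao between −0.21 and 0.06) had −0.03, and cholesterol synthesis genes (Hmgcs1, Cyp51 and Msmo1 between 0.06 and 0.65) 0.13.

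Camera also called none of the stress, immune and growth lists there (lowest adjusted p 0.314, renin-angiotensin). Antioxidant genes (Gpx3, Gpx1, Prdx5 and Prdx1 between −0.33 and 0.08) had a median of 0.03, unfolded protein response genes (Hsp90b1, Hspa5, Calr and Pdia3 between −0.05 and 0.33) 0.02, and immediate early genes (Hspa8, Hsp90aa1, Jund and Jun between −0.25 and 0.28) −0.06. Dnajb1, of the last list, had a log2 fold change of −1.81 and an edgeR adjusted p of 0.0343 when adjusted over the list alone, but did not pass over all genes. It had 6 and 5 UMIs in the Akita libraries and 15 and 30 in the wild-type libraries. Its level was 42.6 CPM in Wild-type replicate 2 against 18.5 CPM in Wild-type replicate 1. Inflammation and antigen presentation genes (B2m, H2-D1, H2-K1 and Cd74 between −0.32 and 0.06) had −0.04 and the renin-angiotensin genes (Ctsa, Mme and Enpep between 0.06 and 0.60) 0.09. Tubular injury genes had 0.15 (Spp1, Clu and Krt8) and matrix genes 0.02 (Timp3, Col4a2 and Col4a1), with 3 tested members each, too few for camera. Cell cycle genes (H2afz, Pcna, Hmgb2 and Tyms between 0.00 and 0.30) had 0.01, ribosomal protein genes (Rpl41, Rplp1 and Rps29 between −0.06 and 0.08) 0.02 against a downward camera rank, and solute transporters (Slc34a1, Lrp2, Slc22a6 and Slc4a4 between 0.01 and 0.12) 0.05, also against a downward rank. Haemoglobin genes (Hbb-bs, Hba-a1, Hba-a2 and Hbb-bt between 0.19 and 0.54) had 0.32, against a downward rank. Grb10 was the only juvenile growth gene tested (−0.41), Y-linked genes had 0.11, and no X-inactivation gene was detected.

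Sex-dimorphic genes gave the only list past camera's threshold in the files as deposited. In proximal tubule-like cells all 4 tested genes that are higher in female mouse kidney (Cyp4a14, Cyp2a4, Prlr and Slc22a19) had higher values in Akita, with log2 fold changes between 0.22 and 1.06 and a median of 0.36 (camera adjusted p 0.0195). With an estimated correlation the camera adjusted p was 0.713, by fry 0.994 and with the replicate block 0.109, so the call did not hold. Leaving out Akita replicate 2 or Wild-type replicate 2 also ended it (camera adjusted p 0.565 and 0.714, the latter with the list ranked downward), while it held without Akita replicate 1 (4.28e-06) and without Wild-type replicate 1 (0.00371). Cyp2a4 was the 1 member past 0.05 adjusted over the list alone, and 0 members passed over all genes. Genes higher in male kidney (Kap, Cyp2e1, Cyp4b1 and Slc7a13 between −0.42 and 0.35) had a median of 0.01 against a downward camera rank (adjusted p 0.982). In the whole suspension camera called 0 of 20 lists, the lowest adjusted p being 0.0825 for the female-higher list (median 0.32). The male-higher list had 0.926 there (median −0.06).

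Keeping each shared barcode in 1 file, camera called 3 lists in the whole suspension, each with an adjusted p of 0.0379. The fatty acid oxidation list was lower in Akita (20 of 27 genes, median −0.24), as was the glucose and fructose handling list (7 of 7, median −0.35), and the cholesterol synthesis list was higher (7 of 9, median 0.55). With an estimated correlation all 3 had a camera adjusted p of 0.840. In proximal tubule-like cells alone none of the 3 was called (camera adjusted p 0.238, 0.238 and 0.0958, medians −0.12, −0.20 and 0.53). With the replicate block as well, the glucose and fructose handling and cholesterol synthesis lists had a camera adjusted p of 0.0451 there, and fatty acid oxidation 0.141. The block was not particular to these lists. Gluconeogenesis, glycolysis and unfolded protein response also had 0.0451 by camera, and the male-higher list 0.000158. All list results with each shared barcode kept in 1 file rest on the assumed assignment of shared barcodes. Proximal tubule-like cells were 73.4% of Akita and 80.9% of wild-type cells in this setting, so cell mix can move the whole-suspension values. In proximal tubule-like cells camera then called the male-higher list upward in Akita (6 of 7 genes, median 0.44, adjusted p 0.00775), with an adjusted p of 0.796 under an estimated correlation. The female-higher list had 3 tested members there, too few for camera.

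**Figure D4:**
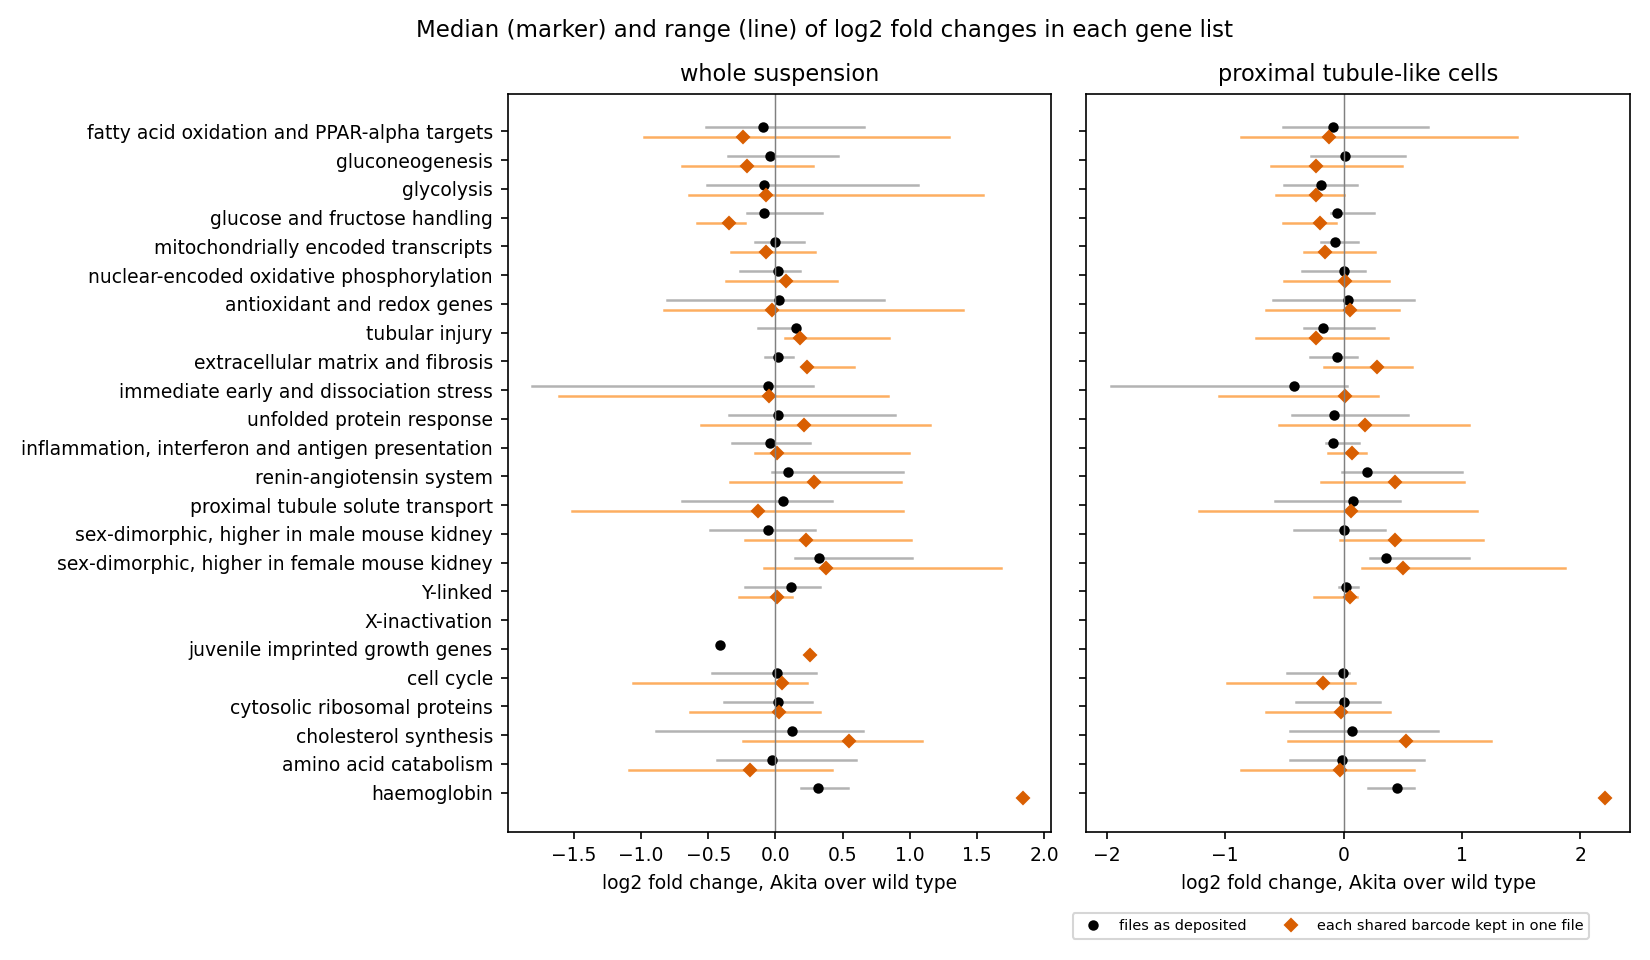
Median (marker) and range (line) of the log2 fold changes, Akita over wild type (x axis), of each gene list in the whole suspension (left) and in proximal tubule-like cells (right), for the files as deposited (black) and with each shared barcode kept in 1 file (orange). The glucose and fructose handling list in the whole suspension has a median of −0.08 in the files as deposited and −0.35 with each shared barcode kept once.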

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

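The test of whether shared barcodes had matching profiles was planned before its result was seen, and the tests of the ratio of UMIs and of the 2 sets were chosen only after it was seen. The 884 barcodes present in both the Akita replicate 2 and the Wild-type replicate 1 file stand out because no other pair of files shared more than 4. They could come from beads with the same barcodes that met unrelated cells, but in 100% of the 156 shared barcodes with at least 1000 UMIs in each file (exact interval 97.7 to 100%) the closest of 564 profiles in the other file was that of the same barcode, with a median correlation across genes of 0.816 against 0.357 for other cells of the class. They could come from 1 library deposited under both names, but the log2 ratios of UMIs had a pair of centres 1.28 apart, which a single library would not have. What stays open is that cells of both libraries are present in both files, for example through reads assigned to the wrong library. The proximal tubule-like counts of the 2 sets of barcodes differed with a chi-square per gene of 8.80, above each of 100 random splits of the same barcodes (median 2.04, highest 2.38), while the same set differed between the files by 0.516 and 0.763, less than independent samples would.

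Which set came from which mouse is not shown by this. Proximal tubule-like cells whose barcodes were only in the Akita replicate 2 file correlated across genes at 0.906 with the set that had relatively more UMIs there and at 0.841 with the other set. For Wild-type replicate 1 the values were 0.858 and 0.756. Intercalated-like cells made up 10.7% of the first set and 0.505% of the second, and proximal tubule-like cells 65.2% and 84.8%. No biological explanation was tested for the sharing itself.

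The string made only of undetermined bases held exactly 1 UMI in each of 11966 genes in Akita replicate 1, 11236 in Akita replicate 2, 12318 in Wild-type replicate 1 and 12607 in Wild-type replicate 2. It is not a cell and was used in no comparison.

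Barcodes outside the retained cells with at least 10% of their UMIs from Hbb-bs, Hbb-bt, Hba-a1 and the other haemoglobin genes numbered 24 in Akita replicate 2, 7 in Wild-type replicate 1 and 7 in Wild-type replicate 2. Akita replicate 1 had 3. They held between 83.6% and 89.4% of each file's haemoglobin UMIs, and 6 of those in Akita replicate 2 were shared with Wild-type replicate 1.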

How the results depend on the processing

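The alternatives on shared barcodes, non-barcode strings, barcodes with the same first 11 bases and the crossed block were chosen only after the data were seen. In the whole suspension and in proximal tubule-like cells, counts of called genes stayed at 0 under other size factors, DESeq2, limma-voom, stricter filters on genes and cells, and thinning. Without a filter on low counts 1 gene (Ces1g) was called in the whole suspension and 1 in proximal tubule-like cells. With 1 library left out, where the lone sample is assumed to vary like the other group, calls ranged from 0 (without Wild-type replicate 2) to 23 (without Akita replicate 2) in the whole suspension, 0 to 12 (without Wild-type replicate 1) in proximal tubule-like cells and 0 to 17 (without Akita replicate 2) in loop of Henle-like cells. The replicate numbers tie the samples to no shared animal, litter or day. Deviations of same-numbered libraries correlated across genes at −0.114 and −0.126 in the whole suspension and in proximal tubule-like cells of the files as deposited. Cells counted in both Akita replicate 2 and Wild-type replicate 1 by themselves draw these values below 0, so they cannot show whether same-numbered libraries deviate alike. With each shared barcode kept in 1 file the values were 0.406 and 0.360. With the replicate block 0 genes were called in each (75, 64 and 10 in loop of Henle-like cells at unadjusted p under 0.05), but with each shared barcode kept in 1 file as well, edgeR called 3 in proximal tubule-like cells, Defb29, Cyp2a4 and Lpar6, where DESeq2 and limma-voom with the block called 0. Pairing the numbers crosswise called 0 genes in the whole suspension, 0 in proximal tubule-like and 0 in loop of Henle-like cells.

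With 1 library left out, camera called from 5 to 9 lists in the whole suspension and 3 to 5 in proximal tubule-like cells. Each of these fits leaves 1 group with 1 library. Leaving out Akita replicate 2 or Wild-type replicate 1 also takes away the overlap of cells between the groups. The list counts rose whichever library was left out, so they do not show that single libraries decide the calls. The replicate block called 1 in the whole suspension, haemoglobin, and the paired count in proximal tubule-like cells was again 1, but haemoglobin in place of the female-higher list (adjusted p 0.109). Keeping each shared barcode in 1 file called 3 in the whole suspension, while proximal tubule-like calls fell to 0 with an estimated correlation, 0 with fry and 0 without shared barcodes. The Akita minus wild-type share of proximal tubule-like cells was −4.94 points with libraries clustered separately, −8.54 without shared barcodes and −7.52 with each kept once, and the difference in median UMIs was 74.0 with at least 500 genes per cell. The cause of these was not tested.

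A direction counts as reversed only where a value was called. Hbb-bs ranged from −1.95 (without Akita replicate 2) to 1.28 and Hbb-bt from −4.06 to 2.08 on the log2 scale. For lists that reversed, camera's adjusted p with 1 library left out ranged in the whole suspension from 0.0145 to 0.731 (gluconeogenesis), 0.0145 to 0.566 (mitochondrially encoded), 1.63e-07 to 0.0219 (oxidative phosphorylation), 0.000304 to 0.307 (inflammation), 0.00188 to 0.639 (ribosomal) and 8.64e-29 to 0.0133 (haemoglobin). In proximal tubule-like cells it ranged from 0.0230 to 0.981 (gluconeogenesis), 5.09e-06 to 0.0812 (oxidative phosphorylation), 0.0230 to 0.0998 (male-higher), 4.28e-06 to 0.714 (female-higher), 0.0216 to 0.800 (ribosomal) and 4.73e-32 to 0.0164 (haemoglobin). Haemoglobin also reversed with the replicate block (0.000100 and 5.66e-08 in proximal tubule-like cells), and the male-higher list with each shared barcode kept in 1 file (0.00775). Changes of sign in values called neither way are left aside (228 whole-suspension values, in 66 of 96 named genes). Of the other values of single genes, lists, shares and library measures, 2886 kept their side of the threshold or stayed within the spread between replicates, 42 moved past the threshold, 4 lost it (the female-higher list in proximal tubule-like cells) and 16 shares or library measures moved by more than that spread. Of the counts of called genes and lists, the share of proximal tubule-like cells and the median UMIs, 74 values stayed, 20 counts rose, 3 counts fell and 4 values moved. At this depth 2-fold changes were recovered in part in simulated independent libraries, so smaller ones can be missed. In the files as deposited, cells counted in both groups can hide larger changes too.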

Other observations

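The test of the mix of proximal tubule-like clusters was planned before its result was seen, and the tests of exchanged cells and of a shared preparation were chosen only after it was seen. Keeping each shared barcode in 1 file, itself a choice made after the data were seen, edgeR called 57 of 5280 genes in proximal tubule-like cells between the libraries numbered 1 and those numbered 2 (21 higher and 36 lower in number 1). It called 0 between Akita and wild type and 0 for the remaining split of the 4 libraries. Which split is called can depend on the assumed assignment of shared barcodes. The opposite assignment would exchange most cells of Akita replicate 2 and Wild-type replicate 1, and values with it were not computed. In the files as deposited all 3 splits of proximal tubule-like cells called 0.

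The genes of this split, chosen after their values were seen, included genes of the list higher in male mouse kidney. Cyp4b1 had 1312 and 1105 CPM in the number 1 libraries of Akita and wild type and 2570 and 3076 CPM in the number 2 libraries (log2 fold change of number 1 over number 2 −1.28). Acsm3 (−2.29), the lipoprotein lipase gene Lpl (−2.37), Ly6e (−5.74), Ly6a (−1.92) and the transthyretin gene Ttr (−3.13) were also lower in number 1. The cell cycle inhibitor gene Cdkn1a (3.62), the aldehyde dehydrogenase gene Aldh1a7 (3.97), which has close paralogs, and Dnase1 (1.89) were higher in number 1. Camera ranked the male-higher list lower in number 1 (median −1.28, adjusted p 8.47e-14), the unfolded protein response list lower (median −0.44, adjusted p 0.00147), and the gluconeogenesis (median 0.50, adjusted p 7.77e-05) and glucose and fructose handling lists higher (median 0.36, adjusted p 0.00173). All 4 calls were lost with an estimated correlation (adjusted p 0.591 for the first pair of lists and 0.686 for the second). The cluster led by Slco1a1, Lpl and Slc7a13 made up 6.53% and 2.20% of proximal tubule-like cells in the number 1 libraries and 19.7% and 9.29% in the number 2 libraries.

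Akita minus wild-type differences ran opposite in the 2 pairs of Akita and wild-type libraries, replicate 1 with replicate 2 and replicate 2 with replicate 1. Their correlation across genes was −0.355 (bootstrap interval −0.426 to −0.290). The bootstrap drew genes, so its intervals do not cover the spread between mice. On edgeR's log2 CPM the correlation was −0.324, against 0.0564 for same-numbered pairs. In the files as deposited it was −0.297 against −0.355. Akita replicate 2 and Wild-type replicate 1 hold mostly the same cells there. They enter the 2 same-numbered differences with opposite signs, which by itself draws that correlation below 0. The values as deposited therefore cannot compare the pairings. Another mix of proximal tubule-like clusters may contribute. With every cluster weighted alike the correlation was −0.194 (bootstrap interval −0.252 to −0.131), so differing shares of these clusters alone do not account for all of it. The cluster led by Slco1a1, Lpl and Slc7a13 had 6 cells (5011 UMIs) in Wild-type replicate 1 and 16 cells (10056 UMIs) in Akita replicate 1. Counting error in such small sums can itself weaken these correlations. The step from −0.355 to −0.194 therefore does not show that cluster mix contributes. Within single clusters the correlation was −0.275 (the cluster led by Cyp2e1, Slc22a6 and Ces2c) and −0.163 (led by Spp2, Slc5a12 and Gatm). It lay between −0.0724 and 0.0524 in the other 4, so the pattern was not seen in each cluster. The cluster at −0.275 had a median of 3370.5 UMIs per cell, against 535 to 785 in the other proximal tubule-like clusters. The weighting does not remove a mix of cells inside a cluster, so it cannot exclude cell mix as the whole cause. Cells of Akita replicate 2 and Wild-type replicate 1 may have been exchanged (each remaining library was closer to the library of the other group, by a smaller gain in correlation of 0.0189), or libraries with the same replicate number may share a preparation (their deviations correlated across genes at 0.360), but these values come from the same 4 libraries as the split, restate it and support neither. Exchange and shared preparation cannot be told apart, because both give the same split of 2 libraries per group, the labels give no batch and no measured gene marks the genotype, and the biological side, age or genotype, was not tested.

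Lpar6, a lysophosphatidic acid receptor gene, is named after its values were seen. In proximal tubule-like cells with each shared barcode kept in 1 file it had 57.4 and 66.6 CPM in the Akita libraries and 7.13 and 9.05 CPM in the wild-type libraries, from 25, 25, 3 and 5 UMIs (edgeR adjusted p 0.244, and 0.0185 with the replicate block, where DESeq2 gave 1.00 and limma-voom 0.988).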
